A study of Mus musculus with 1778 samples.

How the data were processed

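The deposited table gave counts, per the labels and the values themselves: whole numbers of reads per gene and cell, without molecular identifiers and without normalization. The submitters' processing notes name bcl2fastq 2.18, STAR 2.6 and the mm10 genome. The read counter, the annotation release, the treatment of reads with several map positions and any filter on cells are not given in the sources used here. The table held 24920 genes, 92 spike-ins and 1778 cells, and each cell is 1 sample of the series. Stages were taken from the labels. The 7-digit number in each title was read as the plate, as no number had more cells than the 384 wells of a plate, but the labels do not say what the number means. No unit was changed. Spike-ins were kept out of library sizes. Coordinates are those of the GENCODE vM21 models on the same build, matched by symbol. The annotation is not known to be the authors' own.

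Cells were kept with at least 50000 reads on genes and at least 1500 detected genes, which left out 19, 25, 1 and 5 cells of 4, 6, 8 and 10 somites. A limit of 20% on mitochondrial reads removed nothing, as the table names 0 mitochondrial genes. No doublet caller was run, since single cells had been sorted 1 to a well. The labels name no embryo or litter, so each stage was 1 pool and cells were not used as replicates. Reads were summed over the kept cells of a stage, 0.5 reads were added, and log2 ratios of RPM were taken, with exact Poisson intervals at 95%. Ratios within plates used the plate number shared by 4 and 6 somites, and the one shared by 6, 8 and 10 somites, and 10 against 4 was the sum of 6 against 4 on the first and 10 against 6 on the second. The number shared by 4 and 8 somites was not in the plan fixed for them, and a route over it, 8 against 4 on it plus 10 against 8 on the second, was added after the results were seen. No ratio was formed where both sums held at most 3 reads, and a stage with 0 reads was set at 3 reads to give a bound. That floor rule for ratios was added after the results were seen, and the 15 values it removed are given with the other alternatives.

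The comparisons, 27 gene lists, cell type markers, the naming rule and most alternatives were fixed before the data were examined. The lists were core pluripotency, primed epiblast, neuroepithelium, neural plate border, neural crest specifiers, epithelial junctions, EMT and migration, ectomesenchyme, neuron and glia, anterior identity, posterior identity, S phase, G2M phase, glycolysis and hypoxia, Wnt, FGF, BMP and TGFb, Notch and retinoic acid targets, dissociation stress, endothelium, erythroid, cardiac, endoderm, surface ectoderm and placode, head and paraxial mesoderm, and notochord and floor plate. Some genes stand in more than 1 list, and many crest, plate border and neural plate genes are known in both tissues. A list was summarised over members with at least 5 RPM at some stage, by the median log2 ratio, the number of members at least 2-fold higher or lower, and the percentile of its median among 10000 random lists matched in 20 bins of expression. Named genes were the 12 largest ratios in each direction for 10 against 4 somites and the 6 largest for each consecutive step. They needed at least 50 RPM in the higher stage, at least 1 read in at least 20% of its cells at 50000 reads, and a ratio within plates of the same sign and a size of at least 1. Unnamed gene models, pseudogenes, ribosomal, mitochondrial and sex-linked marker genes were not eligible. Up to 4 members of each list with the largest ratios were also named. Twist1 and Pou5f1 were fixed for the shares of cells and are named throughout. Some genes that the rule named are not reported.

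Shares of cells counted cells with at least 1 read after random thinning to 50000 reads, with exact Clopper-Pearson intervals. Clusters came from Leiden clustering in scanpy on log counts per 10000, 2000 variable genes, 30 components, 15 neighbours and resolution 1, and were named by the fixed markers.

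Alternatives were the mean of RPM per cell, scaling by edgeR TMM factors or DESeq2 size factors (both tools served for scaling alone), no filter on cells, a filter at 200000 reads and 3000 genes, no minimum RPM for list members, 5 added reads, ratios within plates, equal weight per plate number with at least 10 cells, leaving out each plate number, and leaving out cells of other types. Shares were also read at 200000 reads, without thinning, and at 3 reads or more, and clusters at resolutions 0.5 and 1.5, with 1000 variable genes, without cell cycle genes, centred per plate and with another seed.

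The steps were tried on made counts with known changes, set in 50 genes for each fold among 8426 genes. Genes set to 2-fold and 4-fold gave median log2 ratios of 0.98 and 1.98, and genes set to 0.5-fold and 0.25-fold gave −1.01 and −2.02, and every gene lay within 0.25 of its true log2 value. Random lists without a change lay between percentiles 17.0 and 98.7. The trial checks the arithmetic of the ratios and percentiles. It says nothing about errors from differences between plates, embryos or cell types. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.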

Results

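Tomato-labelled cells from the heads of Wnt1::Cre; Rosa26-TdTomato mouse embryos, in which the label marks cells with a history of Wnt1 transcription (the dorsal neural tube and the neural crest), were sorted singly into lysis buffer and sequenced with Smart-Seq2, a plate method that reads whole transcripts without molecular identifiers. Embryos were dissected at 4 stages, 4, 6, 8 and 10 somites. The table held 1778 cells, with 239 cells at 4 somites, 860 at 6, 228 at 8 and 451 at 10. After filtering, 220, 835, 227 and 446 cells of these stages remained, 1728 in all. The kept cells had between 92185 and 2098451 reads on genes, with a median of 859223. The median was 1117607 reads at 4 somites, 847071 at 6, 909712 at 8 and 768600 at 10, and the median number of detected genes was 6845.5, 6506, 7724 and 7520.5. The reads summed over the cells of a stage came to 242, 738, 212 and 349, in units of 1000000 reads. The 45S pre-ribosomal RNA, Rn45s, took 54.4% of all reads of the kept cells, from 44.4% at 8 somites to 59.2% at 6.

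The cells carried 8 plate numbers in their titles, and no plate number held cells of all 4 stages. Of the kept cells, 1 plate number held 128 of 4 and 180 of 6 somites. Another held 72 of 6, 212 of 8 and 55 of 10 somites, and another held 92 of 4 and 15 of 8 somites. No embryo is named in the labels, so each stage was 1 pool of cells, no check across replicates could be made, and no test was run. Stages were compared by the log2 ratio of RPM, the summed reads of a gene scaled to a total of 1000000 reads per stage, and each ratio is given with the ratio within plate numbers, which uses the first and the second of these numbers and for 10 against 4 somites is chained over both. The number with 15 cells of 8 somites was read separately, after the other results were seen. Intervals are 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. The spread between plates was taken as the SD of a list's mean log2 RPM over the 5 plate numbers with cells of 6 somites. It is the spread of a single mean. A difference between stages, or a chain of them, varies more, so this SD is a narrow yardstick. The median gene, among 3973 genes with at least 20 RPM at every stage, had a log2 ratio of 0.17 for 10 against 4 somites (−0.29 within plates), −0.13 for 6 against 4 (−0.32), 0.45 for 8 against 6 (0.11) and −0.16 for 10 against 8 (−0.08). List medians are therefore also given relative to the median gene.

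The comparison of 10 against 4 somites asks how the labelled cells differed between the ends of the series, and in particular whether factors of the pluripotent state were transcribed before the cranial neural crest had formed and lost afterwards. Pou5f1 (Oct4), a core transcription factor of pluripotent cells, stood at 11.8 RPM (11.4 to 12.2) at 4 somites, 4.26 (4.11 to 4.41) at 6, 0.273 (0.208 to 0.353) at 8 and 0.166 (0.126 to 0.215) at 10. Its log2 ratio of 10 against 4 somites was −6.14 (−4.22 within plates). Nanog, its partner in pluripotent cells, was at 5.616, 1.64, 0.0707 and 0.0687 RPM, with a log2 ratio of −6.32 (−6.00 within plates). Fgf5, a marker of the primed epiblast, had a ratio of −6.82 (−6.77 within plates). Sox10, a transcription factor of the migrating neural crest, went the other way, from 6.86 RPM (6.53 to 7.20) at 4 somites to 42.5 at 6, 173 at 8 and 142 (141 to 143) at 10, with a log2 ratio of 4.37 (1.07 within plates). On another route within plates, by way of 15 cells of 8 somites, the ratio was −1.52 for Pou5f1, −2.31 for Nanog and 2.28 for Sox10, so the directions held and the sizes did not.

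Of 17 core pluripotency genes, 6 reached the 5 RPM needed at some stage, Pou5f1 and Nanog at 4 somites alone. The others, such as Klf4 at 1.44 RPM or less, stayed below it at every stage. Of the 6 measured genes, 4 were at least 2-fold lower at 10 than at 4 somites, Sall4 among them at −1.29 (−1.48 within plates), and 1 was higher. The higher one was Tbx3, a T-box factor with later roles in the embryo, at 6.19 (3.92 within plates). The list median was −1.20, which was −1.37 relative to the median gene (−1.29 within plates), a larger distance than the plate SD of 0.587. The 2 plate numbers of 4 somites stood apart, however, with list means of 2.02 and 4.40 in log2 RPM. On those of 8 and 10 somites the means were 2.28 to 2.49, so 1 of the former was not higher. The number with the mean of 4.40 also had the higher mean of dissociation stress genes, 4.88 against 1.11. Pou5f1 was at 3.06 and 18.69 RPM on these 2 plate numbers and at most 0.597 on those of 8 and 10 somites. Of 10 primed epiblast genes, 6 were at least 2-fold lower and 0 higher, with Otx2 at −1.77 (−1.87) and Dnmt3b, a DNA methyltransferase, at −1.63 (−1.66). Their median was −1.69 relative to the median gene (−1.25 within plates). Without the plate number that held 128 of the 220 cells of 4 somites, the core pluripotency median was −0.61, or −1.11 relative to the median gene.

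Genes of the neural plate, its border and of anterior and posterior identity were read next. Of 14 neuroepithelium genes, 7 were at least 2-fold lower, with Pax2 at −4.45 (−1.90 within plates), Sox21 at −2.15 (−2.28) and Wnt1 at −1.88 (−1.71), 5 were neither, and 2 were higher, with Nes, an intermediate filament of neural progenitors, at 1.89 but −0.56 within plates. The neuroepithelium median was −0.91, or −1.07 relative to the median gene (−0.34 within plates, and −0.256 by way of 8 somites), beyond the plate SD of 0.143, and relative to the median gene it was −0.77 without the plate number with 128 cells of 4 somites and −0.90 without the one with 379 cells of 10 somites. Of 9 anterior identity genes, 7 were at least 2-fold lower and 0 higher, with Hesx1 at −3.84 (−2.43), En1 at −2.33 (−1.85) and Dmbx1 at −2.24 (−0.94), and their median was −2.21 relative to the median gene (−1.56 within plates). Of 9 neural plate border genes, 4 were lower, with Gbx2 at −1.81 (−2.33), Zic5 at −1.58 (−2.16) and Dlx5 at −1.17 (−2.71), and the median was −0.90 relative to the median gene (−1.87 within plates). Of the 4 measured posterior identity genes, 2 were higher, with Hoxb1 at 2.26 (2.20 within plates), and 2 lower, with Egr2 at −1.79 (−1.43), and their median was 0.07 relative to the median gene. The direction of Egr2 was open, as it was at 3.27 without the plate number with 128 cells of 4 somites and at 7.349 within plates by way of 8 somites.

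Most neural crest and ectomesenchyme genes measured were higher at 10 somites in all cells. Of 15 neural crest specifiers, 11 were at least 2-fold higher and 1 lower, with Erbb3, a neuregulin receptor, at 4.31 (2.32 within plates), Sox5 at 3.64 (1.80) and Tfap2b at 3.619 (2.184). Their median was 2.89, or 2.72 relative to the median gene (1.22 within plates), against a plate SD of 0.831. Of 15 ectomesenchyme genes, which mark the crest cells that form the facial skeleton, 11 were at least 2-fold higher and 1 lower, with Dlx2 at 5.32 (3.49) and Col1a2 at 4.68 (0.75), whereas Col3a1 was at 5.72 but −0.82 within plates. The ectomesenchyme median was 2.12, or 1.95 relative to the median gene (1.55 within plates), against a plate SD of 0.438. Twist1, a crest and mesenchyme factor in both lists, was at 3.475 (1.624 within plates). Of 17 genes of epithelial-mesenchymal transition (EMT) and migration, 8 were at least 2-fold higher and 1 lower, with Itga4 at 3.96 (2.48), Snai1 at 2.619 (0.41), Tgfbi at 1.84 (0.85) and Vim at 2.47 but −0.04 within plates, and their median was 0.77 relative to the median gene (0.42 within plates). Of 8 epithelial junction genes, 5 were lower, with Cdh1 (E-cadherin) at −2.41 (−0.40), Epcam at −2.14 (−1.87), Esrp1 at −1.88 (−2.64) and Cldn6 at −1.35 (−0.30), and their median was −1.44 relative to the median gene but −0.06 within plates. These 4 genes also marked the surface ectoderm-like cluster, whose share of cells was 10.5% at 4 and 1.57% at 10 somites. Without the cells of other types, that cluster among them, the junction median was −2.19 relative to the median gene, with Cdh1 at −4.15 and Epcam at −3.36. Of 6 neuron and glia genes, 3 were higher, 2 of which also stand among the crest specifiers, and Stmn2 was at −2.10 (−2.87). That list's median was 1.77 relative to the median gene and 0.16 within plates.

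Of the 27 gene lists, 6 lay above the median gene by more than their plate SD, 9 lay below it by more than their plate SD, and 12 lay within it. In the ratios chained within plates all 15 kept that side of the median gene of the chain, and 11 lay beyond their plate SD. Some of the 11 lay only a little beyond that narrow yardstick. EMT was at 0.42 against 0.352, FGF targets at 0.33 against 0.283, and notochord and floor plate at −1.69 against 1.31. The 4 inside it were epithelial junctions (SD 0.413), neuron and glia (SD 0.803), BMP and TGFb targets (SD 0.256), and surface ectoderm and placode (SD 0.591). By way of 8 somites 10 lay beyond it, and ectomesenchyme and the BMP and TGFb targets were on the other side. Before the median gene was subtracted, neuron and glia and BMP and TGFb targets, 2 of the 6 above, lay at −0.13 and −0.234 in the chain by way of 6 somites. The medians of the neural crest specifiers, ectomesenchyme, EMT, and neuron and glia lists lay at percentile 100 of 10000 random lists matched for size and expression, and that of core pluripotency lay at percentile 0.04. Lists inside their plate SD could lie as far out, with glycolysis and hypoxia at percentile 0 and G2M phase at 0.215. The percentile takes no account of the spread between plates.

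On the plate number with 92 cells of 4 and 15 of 8 somites, the log2 ratio of 8 against 4 somites was −2.36 for Pou5f1 (11 and 325 reads), −2.23 for Nanog, −0.345 for Fgf5, −2.59 for Pim2, 2.591 for Sox10, 2.78 for Dlx2 and 3.305 for Mef2c. Relative to the median gene, the list medians on it were 1.09 for neural crest specifiers, −0.843 for core pluripotency, −5.18 for epithelial junctions, 0.304 for primed epiblast, 0.00229 for neuroepithelium and −0.0366 for ectomesenchyme. The surface ectoderm and placode list lay at −3.15 there. Surface ectoderm-like cells were 12 of the 92 (13.04%) and 0 of the 15, and neuroepithelial-like cells 41 (44.6%) and 13 (86.7%), so the epithelial junction value may follow the mix of cells. The primed epiblast, neuroepithelium and ectomesenchyme lists did not follow the direction they had in all cells. Chained with 10 against 8 on the other number, this route gave medians for 10 against 4 somites, relative to the median gene, of 1.42 for neural crest specifiers, −0.99 for core pluripotency, −0.41 for primed epiblast, −0.26 for neuroepithelium and −0.03 for ectomesenchyme.

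**Figure D1:**
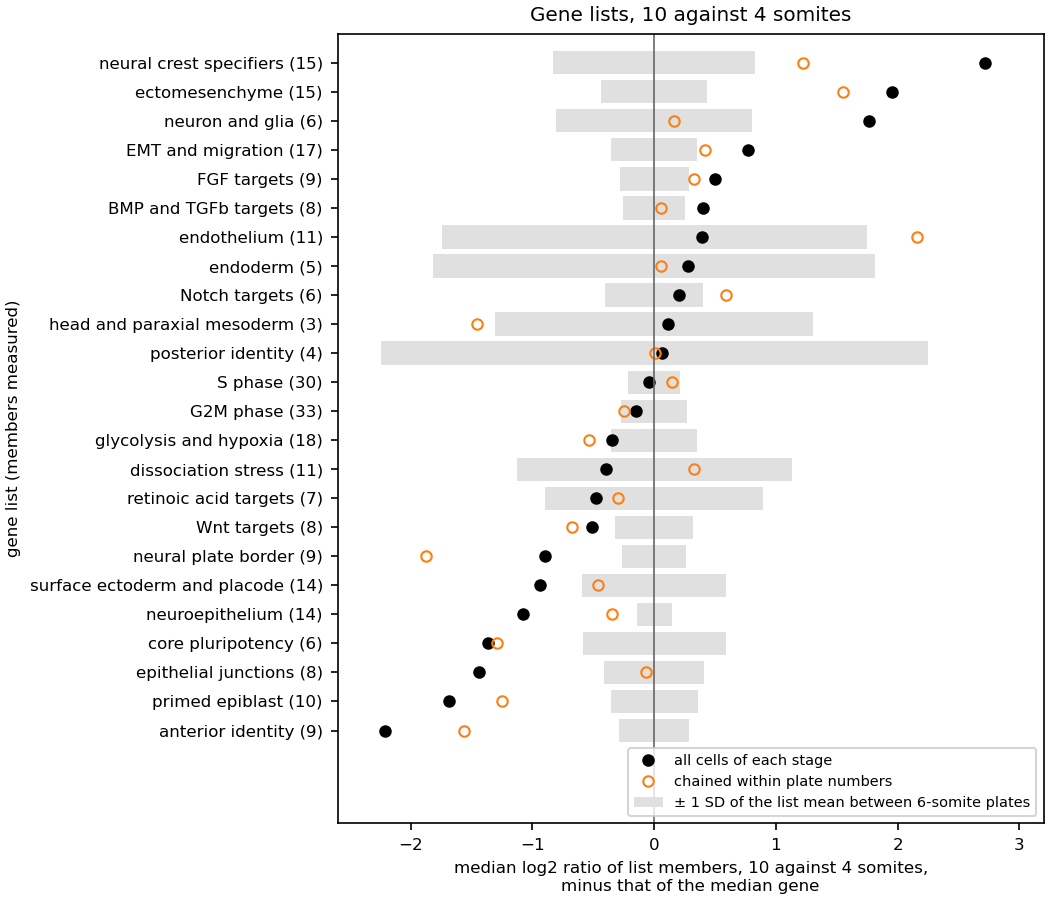
Median log2 ratio of the members of each gene list, 10 against 4 somites, minus that of the median gene (x axis), for lists with at least 3 measured members (y axis, number in brackets, erythroid genes left out). Black dots are all cells of each stage, open dots the ratio chained within plate numbers, and grey bars 1 SD to either side of 0 of the list mean between the plates of 6 somites. Neural crest specifiers lie at 2.72 and anterior identity genes at −2.21.

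By the naming rule, 44 genes were eligible as higher and 67 as lower at 10 somites. The 12 with the largest ratios upward were Mef2c, a transcription factor of craniofacial and heart development, at 5.38 (2.38 within plates), Fam212a at 4.41 (1.43), Sox10, Ngfr, a neurotrophin receptor of crest cells, at 4.23 (1.92), Crabp1, which binds retinoic acid in the cytoplasm, at 4.00 (3.03), Plcg2, a phospholipase, at 3.57 (2.04), Cdc42ep1 at 3.31 (1.30), Rasa3 at 3.05 (1.09), Mcc at 2.96 (1.34), Foxo1 at 2.93 (1.06), Ets1, a factor of cranial crest delamination, at 2.89 (2.08), and Cnn2, an actin-binding calponin, at 2.42 (1.17). The 12 downward included Pim2, a serine/threonine kinase, at −5.65 (−3.31 within plates), Pmaip1 (Noxa), a promoter of apoptosis, at −4.27 (−1.60), Fgf15, a growth factor of the neural tube, at −3.15 (−1.45), Ldhb at −3.08 (−2.30), Ezr (ezrin), a membrane-cytoskeleton linker of epithelia, at −2.71 (−2.51), Shisa2 at −2.63 (−2.01), Lrp2 (megalin), an endocytic receptor of the anterior neuroepithelium, at −2.601 (−1.15), Tubb4a at −2.49 (−3.22), Smtnl2 at −2.43 (−1.91), Socs2 at −2.15 (−2.26) and Slc2a1, the main glucose transporter of embryonic cells, at −2.13 (−1.55). All 24 kept their direction when any 1 plate number was left out. Without the plate number with 128 cells of 4 somites, Sox10 was at 3.64, Pim2 at −4.20 and Pou5f1 at −4.19. Mef2c was at 1.88 RPM (1.71 to 2.06) at 4 somites and 78.3 (77.4 to 79.2) at 10, and Pim2 at 177 (175 to 179) and 3.53 (3.34 to 3.73).

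On mm10 (GRCm38), with 1-based positions of the GENCODE vM21 gene models, Pou5f1 lies on chromosome 17 from 35506018 to 35510772 and Nanog on chromosome 6 from 122707489 to 122714633. Both have processed pseudogenes elsewhere in the genome, and how reads that map to several places were counted is not given in the sources used here. Sox10 lies on chromosome 15 from 79154908 to 79165240, Mef2c on chromosome 13 from 83504034 to 83667080, Twist1 on chromosome 12 from 33957671 to 33959829, and Pim2 on the X chromosome from 7878262 to 7883432. All of these are protein-coding genes.

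**Figure D2:**
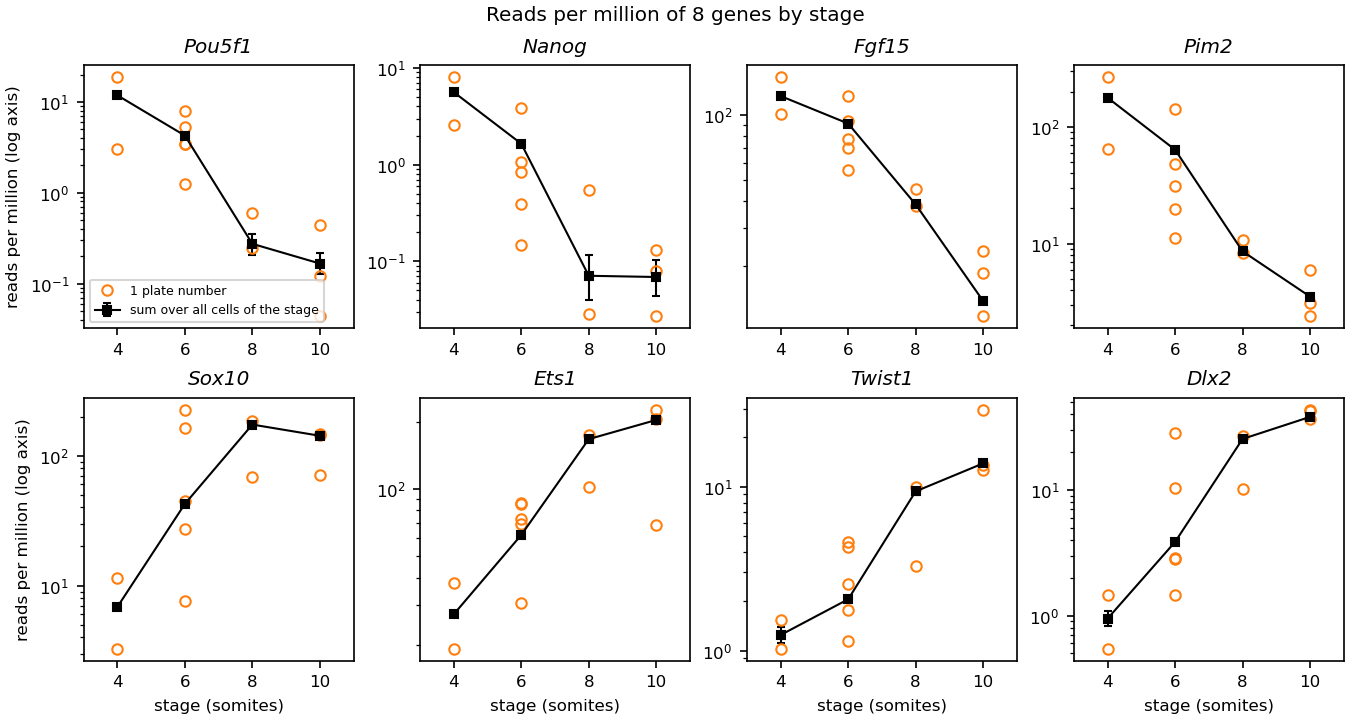
RPM (y axis, log scale) of 8 genes by stage in somites (x axis). Black squares are the sums over all cells of a stage with 95% Poisson intervals, and open circles are single plate numbers with at least 10 cells. Pou5f1 goes from 11.8 RPM at 4 somites to 0.166 at 10, and Sox10 from 6.86 to 142, with a wide scatter between plates at 6 somites.

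Signalling and metabolic lists lay nearer the median gene between 4 and 10 somites than the neural crest specifier, ectomesenchyme and anterior identity lists did. Relative to the median gene, the Wnt target median was −0.51 (−0.68 within plates) with 3 of 8 genes at least 2-fold lower, among them Nkd1 at −1.38 (−2.07) and Sp5 at −1.35 (−2.10), while Tcf7 was at 0.86 but −0.76 within plates. The FGF target median was 0.50 (0.33 within plates), with 4 of 9 genes higher, Il17rd at 1.736 (3.89) and Dusp6 at 1.39 (1.31) among them, and Spry4 at 1.90 but −0.92 within plates. The BMP and TGFb target median was 0.40 (0.06 within plates), with Id1, the single gene of 8 at least 2-fold higher, at 1.42 but −0.26 within plates. The Notch target median was 0.20 (0.59 within plates), with Hes5, the single gene of 6 at least 2-fold higher, at 1.12 but −0.38 within plates. The retinoic acid target median was −0.48 (−0.29 within plates), with 2 of 7 genes higher, Crabp1 among them, and Cyp26a1, which breaks down retinoic acid, at −3.16 (−7.79). The glycolysis and hypoxia median was −0.35 (−0.54 within plates), with 2 of 18 genes lower, Slc2a1 and Slc2a3 at −1.65 (−0.76), and with Pdk1 at 1.06 and Egln3 2-fold higher, both negative within plates at −0.12 and −0.80. None of 30 S phase and 33 G2M phase genes differed 2-fold, with medians of −0.04 (0.14 within plates) and −0.15 (−0.25).

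Lists of other cell types and of handling were also read. Of 14 surface ectoderm and placode genes, 7 were at least 2-fold lower at 10 somites, with Eya2 at −1.89 (−1.46 within plates), and their median was −0.93 relative to the median gene (−0.46 within plates). Of 11 endothelium genes, 5 were higher, with Tie1 at 5.89 (4.57), Plvap at 2.81 (1.87) and Esam at 1.58 (2.84, but −4.028 by way of 8 somites), and the median was 0.39 (2.16 within plates). The medians of the 5 endoderm genes at 0.28 (0.06 within plates) and of the 3 head and paraxial mesoderm genes at 0.11 (−1.45 within plates) lay within their plate SDs of 1.82 and 1.31, and the 2 notochord and floor plate genes were at −1.43 (−1.69 within plates) against 1.31. Among them, Foxa1 was at 3.39 but −1.25 within plates, Tbx1 at 2.41 but −1.29, and Ntn1 at −1.77 (−1.46). Actc1, the single cardiac gene of the list with at least 5 RPM at some stage, was at 1.85 (1.26 within plates, but −7.084 by way of 8 somites). The 3 erythroid genes had 0 reads at 4 somites, so Hba-x, an embryonic globin, was at least 17.5-fold higher at 10 somites (floor of 3 reads over the stage), and the list median with that floor was 3.67, with no ratio within plates. The bound for Hba-x rested on 2 of 55 cells of the plate number shared by 6, 8 and 10 somites and 1 of 379 cells of another. Without the former no ratio could be formed. Of 11 dissociation stress genes, 3 were at least 2-fold lower, with Fos at −2.17 but 1.55 within plates, Egr1 at −2.18 but 1.203 within plates, and Btg2 at −1.24 (−1.33, but 0.2826 by way of 8 somites), and the median was −0.39 (0.33 within plates).

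The comparison of 6 against 4 somites covers the first step. Pou5f1 had a log2 ratio of −1.47 (−1.24 within plates), Nanog −1.77 (−1.05) and Fgf5 −1.03 (−0.60), whereas Sox10 was at 2.63 (1.22), Sox5 at 1.84 (1.05), Tfap2b at 1.67 (1.90) and Dlx2 at 2.02 (1.42). Of 6 core pluripotency genes, 2 were at least 2-fold lower and 1 higher, and their median was −0.83, or −0.69 relative to the median gene (−0.50 within plates). Of 15 neural crest specifiers, 5 were at least 2-fold higher and 0 lower, with a median of 0.86, or 0.99 relative to the median gene (0.37 within plates), and of 14 neuroepithelium genes 0 differed 2-fold, with a median of −0.45, or −0.32 relative to the median gene (−0.0042 within plates). Ectomesenchyme genes had a median of 0.86 relative to the median gene (0.25 within plates), with 4 of 15 at least 2-fold higher. By the naming rule 0 genes were eligible as higher and 11 as lower, among them Fgfr2, a receptor of fibroblast growth factors, at −1.14 (−1.01 within plates), Tubb4a at −1.12 (−1.10), Abr at −0.85 (−1.06), Amotl2 at −0.68 (−1.07) and Ywhag at −0.63 (−1.26). Without the plate number that held both stages, the core pluripotency median was −0.41 and the neuroepithelium median −0.42 relative to the median gene, Amotl2 was at 0.26 and Ywhag at 0.47.

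The comparison of 8 against 6 somites held the largest pooled median of the neural crest specifiers among the consecutive steps. Of 15 neural crest specifiers, 10 were at least 2-fold higher and 0 lower, with Erbb3 at 2.56 (1.45 within plates), Sox10 at 2.03 (0.17) and Twist1 at 2.19 (1.12), and their median was 1.499, or 1.05 relative to the median gene (0.22 within plates). Of 15 ectomesenchyme genes, 11 were higher and 0 lower, with Dlx2 at 2.72 (1.39), and the median was 1.72, or 1.27 relative to the median gene (1.02 within plates). Pou5f1 was at −3.95 (−3.82) and Nanog at −4.49 (−4.87), while the core pluripotency median was −0.02, or −0.47 relative to the median gene (−0.35 within plates), with 2 of 6 genes lower and Tbx3 higher at 3.88 (2.53). The neuroepithelium median was 0.16, which was −0.29 relative to the median gene and 0.15 within plates, with 2 of 14 genes higher and 2 lower. The named genes were led upward, of 46 eligible, by Plcg2 at 2.88 (1.56), Mef2c at 2.64 (1.19), Gpc1, a cell surface proteoglycan, at 2.48 (1.49), Cnn2 at 2.07 (1.61), Vim at 2.01 (1.25) and Nrip1 at 1.98 (1.07), and downward, of 7 eligible, by Fos at −3.98 (−1.63), Pim2 at −2.88 (−1.90), Fgf15 at −1.25 (−1.03), Shisa2 at −1.21 (−1.37), Ezr at −1.04 (−1.33) and Smtnl2 at −0.86 (−1.10). The step rested on the plate number that held 212 of the 227 cells of 8 somites, since the 15 cells left without it gave medians of 0.77 for the neural crest specifiers, −0.52 for ectomesenchyme, −0.76 for core pluripotency and 0.41 for neuroepithelium, and ratios of −0.37 for Cnn2, 0.10 for Smtnl2 and −11.65 for Fos.

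The comparison of 10 against 8 somites held the smallest pooled median of the neural crest specifiers among those steps. Within plates that of 6 against 4 was smaller (0.042 against 0.086) before the median gene was subtracted. None of 15 neural crest specifiers differed 2-fold, and their median was 0.04, or 0.21 relative to the median gene (0.17 within plates), with Sox10 at −0.29 (−0.32). Of 14 neuroepithelium genes, 3 were at least 2-fold lower and 0 higher, with Wnt1 at −1.10 (−0.62), and the median was −0.56, or −0.40 relative to the median gene (−0.39 within plates). Primed epiblast genes were at −0.72 and anterior identity genes at −0.80 relative to the median gene (−0.51 and −0.55 within plates), each with 4 genes at least 2-fold lower. None of 6 core pluripotency genes differed 2-fold, and their median was −0.26, or −0.10 relative to the median gene. No gene was eligible as higher, and the 3 eligible as lower were Col18a1, a collagen of basement membranes, at −1.06 (−1.33), Colec12 at −0.77 (−1.46) and Lars2, a mitochondrial tRNA synthetase, at −0.61 (−1.89). Without the plate number shared by 6, 8 and 10 somites, the neural crest specifier median was 1.17 (0.83 relative to the median gene), and that of 8 against 6 in the same setting was 0.77 (0.82). The neuroepithelium median was then −0.94 (−1.285) and Colec12 was at 0.25. Without the one with 379 cells of 10 somites the neuroepithelium median was −0.35.

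Shares of cells with a transcript were read after thinning every cell to 50000 reads. Pou5f1 was seen in 67 of 220 cells at 4 somites (30.5%, exact Clopper-Pearson interval 24.5 to 37.0), 108 of 835 at 6 (12.9%, 10.73 to 15.4), 2 of 227 at 8 (0.881%, 0.107 to 3.15) and 2 of 446 at 10 (0.448%, 0.0544 to 1.61). Without thinning these shares were 58.6%, 30.2%, 6.61% and 5.61%. On the 2 plate numbers of 4 somites the thinned Pou5f1 share was 13.04% of 92 cells and 43.0% of 128 cells, and on the 5 of 6 somites it ran from 5.32% to 24.4%. On the plate number that held both stages the share was 43.0% at 4 and 24.4% at 6 somites. Nanog was seen in 14.5%, 4.43%, 0.441% and 0.224% of cells at 4, 6, 8 and 10 somites, Sox2 in 51.4%, 33.7%, 32.6% and 27.6%, Klf4 in 5.45%, 1.56%, 1.32% and 1.79%, and Lin28a, an RNA-binding protein of early embryos, in 97.3%, 91.9%, 95.2% and 92.6%. Sox10 was seen in 8.64%, 29.0%, 67.4% and 76.7%, Twist1 in 5.91%, 6.23%, 32.2% and 39.5%, Wnt1 in 40.9%, 31.5%, 18.1% and 12.3%, Foxd3, an early crest specifier, in 9.09%, 11.4%, 12.3% and 8.744%, and Prrx1, a mesenchyme factor, in 18.64%, 11.1%, 13.2% and 26.0%. The Foxd3 shares depended on depth, with 16.8%, 20.1%, 30.8% and 20.72% at 200000 reads and 19.5%, 27.5%, 41.0% and 32.3% without thinning.

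As a background, genes of other cell types were read in the same way. Hbb-bh1 was seen in 0 of 220 cells at 4 somites, which allows a share of up to 1.36%, and in 1.44%, 4.85% and 0.448% at 6, 8 and 10 somites. The limit of a count of 0 was taken as 3 cells of the total. That is tighter than the upper end of the exact interval used for the other shares. Myl7, a cardiac myosin light chain, was seen in 5.91%, 2.40%, 0.881% and 0.448%, Cdh5 in 0.909%, 2.75%, 3.96% and 3.59%, and Ttr in 0, 0.240%, 0.441% and 0%, the last of which allows a share of up to 0.673% by the same limit. At 50000 reads the Pou5f1 shares at 8 and 10 somites were thus no higher than those of Myl7, with 2 cells each. Without thinning Pou5f1 was seen in 15 of 227 and 25 of 446 cells and Myl7 in 22 and 17. Myl7 itself stood at 2.14, 3.39, 0.189 and 0.0744 RPM at 4, 6, 8 and 10 somites. Its log2 ratio of 10 against 4 was −4.82 (−0.62 within plates), so a gene of another cell type was also lower at 10 somites. At 4 somites it was seen in 9.4% of 128 cells and 1.1% of 92, and Pou5f1 was also more frequent on the former plate number. Cells with 2 transcripts were set against the product of the single shares, taken within each plate number and summed, since those shares differed between plates. At 4 somites 16 cells (7.27%) held both Pou5f1 and Nanog, where 12.2 are expected (9.75 from the pooled shares). There 1 cell (0.455%) held both Pou5f1 and Sox10, where 3.67 are expected (5.79 pooled). At 6 somites the shares with both were 0.958% for Nanog (0.754% expected), 6.11% for Sox2 (4.61%) and 2.40% for Sox10 (3.26%). Without thinning, cells with both Pou5f1 and Sox10 made up 10.0% at 4 somites (8.996% expected) and 11.1% at 6 somites (10.63%). The deficit of Sox10 among cells with Pou5f1 was not seen at full depth.

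**Figure D3:**
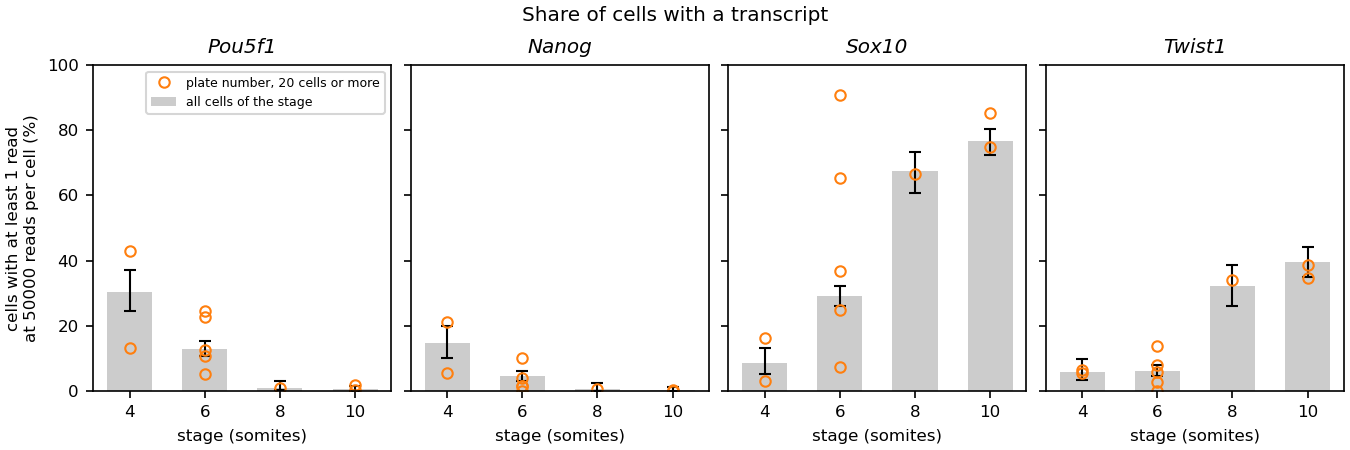
Share of cells (y axis, %) with at least 1 read of Pou5f1, Nanog, Sox10 or Twist1 after thinning to 50000 reads, by stage in somites (x axis). Bars are all cells of a stage with 95% Clopper-Pearson intervals, and circles are plate numbers with at least 20 cells. Pou5f1 goes from 30.5% at 4 somites to 0.448% at 10, and Sox10 from 8.64% to 76.7%.

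Leiden clusters were named by the markers they carried, as types that cells resembled. Neuroepithelial-like clusters held 557 cells (32.2%), early crest-like clusters 456 (26.4%), a mesenchymal-like cluster 68 (3.94%), a surface ectoderm-like cluster 135 (7.81%), endothelial-like clusters 86 (4.98%), and 426 cells (24.65%) were in clusters whose markers gave no single name. Neuroepithelial-like cells made up 61.8% of cells at 4 somites, 36.9% at 6, 21.1% at 8 and 14.57% at 10, and early crest-like cells 10.0%, 22.04%, 34.8% and 38.3%. Over 7 other settings of the clustering the neuroepithelial-like shares ran from 50.9% to 75.0%, 25.6% to 52.57%, 10.1% to 21.59% and 5.38% to 12.1%. The early crest-like shares ran from 2.27% to 15.5%, 14.97% to 26.8%, 18.1% to 52.0% and 28.7% to 45.5%. The early crest-like share at 10 somites was above that at 4 in all 8 settings and above that at 8 in 5 of them. On the 2 plate numbers of 4 somites, early crest-like cells were 2 of 128 and 20 of 92. On 2 plate numbers of 6 somites they were 1 of 22 and 1 of 72, although Sox10 was seen in 90.9% and 65.3% of those cells. Most cells there were in clusters without a name. The early and late stages filled different clusters of the same name. One early crest-like cluster, led by Sox9, Wnt1 and Pax3, held 22 cells of 4 somites and 184 of 6, and the other, led by Plcg2, Ets1 and Sox10, held 240 cells, none of them from 4 or 6 somites. Cells of the mesenchymal-like cluster were 64 of 446 at 10 somites (14.3%, 11.2 to 17.9), 0.479% at 6, and 0 at 4 and 8, which is not a count of all cells with mesenchymal markers. That cluster raised 4 of these markers. A cluster without a name, with 11, 47, 16 and 21 cells of 4, 6, 8 and 10 somites, raised 10 beside 4 mesodermal ones. Another, with 66 cells of 10 somites and 2 of 8, raised 7, and the later early crest-like cluster raised 7 beside 7 crest markers. All 64 cells came from 1 plate number, and the share was 0 when values were centred per plate, when Rn45s was left out before clustering, or without that plate number. Surface ectoderm-like cells were 10.5%, 11.4%, 4.41% and 1.57% of cells, and endothelial-like cells 2.27%, 5.15%, 4.85% and 6.05%. Over the other settings the endothelial-like shares ran from 3.95% to 5.15% at 6 somites and from 2.47% to 6.05% at 10. Whether the share at 10 somites lay above that at 6 thus depended on the setting.

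**Figure D4:**
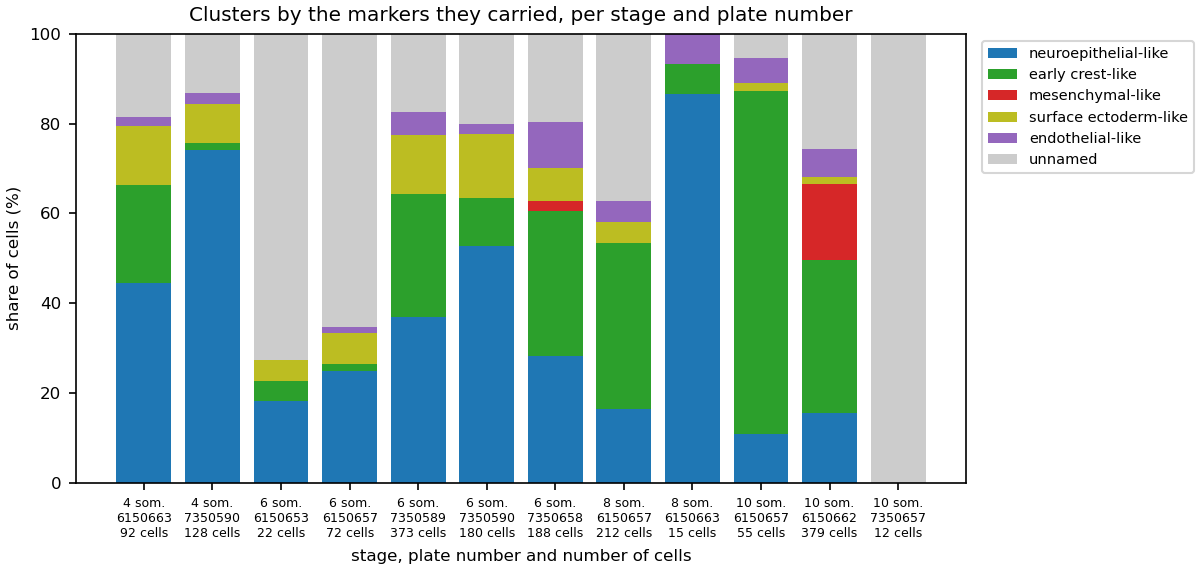
Share of cells (y axis, %) in clusters of each name, for every stage and plate number (x axis, with the number of cells). Mesenchymal-like cells make up 16.9% of the 379 cells of the largest plate number of 10 somites and 2.13% on 1 plate number of 6 somites, and neuroepithelial-like cells are the largest named group on both plate numbers of 4 somites.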

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

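The tests of a plate batch for Pou5f1, of Pou5f1 inside single clusters and of library depth for the plates of 6 somites were chosen only after the result was seen. Each of the following values was marked because it came from data outside the main measurement, the spike-ins, Y-linked genes or genes of other cell types, and stood above the limit that a count of 0 allows. Spike-ins took a median of 2.80% of reads in cells of 6 somites on 1 plate number and 0.291% in cells of 4 somites on the same plate number. On the number shared by 6, 8 and 10 somites the medians were 0.236%, 1.21% and 1.64%, and on the one shared by 4 and 8 somites 1.44% and 1.45%. Ddx3y, a Y-linked gene, was seen in 44.2% of cells at 10 somites, 43.6% at 8, 23.4% at 6 and 8.18% at 4, while Xist was seen in 0 of 446 cells at 10 somites, 0.881% at 8, 35.9% at 6 and 50.9% at 4. Hba-x, an embryonic globin, was seen in 16.67% of the 72 cells of 6 somites on 1 plate number.

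Pou5f1 was highest, in RPM, at 4 somites. A falling share of neuroepithelial-like cells is argued against as the whole cause, since the log2 ratio of 10 against 4 somites was −5.54 within those cells alone. They were not 1 uniform class, as 1 of their clusters had 59 cells of 4 and 0 of 10 somites and another 0 and 42, but in the 2 clusters with cells of both stages Pou5f1 had 599 reads in 48 cells of 4 somites and 2 reads in 16 of 10, and 210 reads in 29 cells and 0 in 7. The share of reads on Rn45s was 55.0% at 4 and 50.1% at 10 somites. Leaving Rn45s out of the totals shifts every gene alike by an amount set by these shares. The resulting ratio of −6.29 is therefore no separate test, but the shares are too alike to give a ratio of this size. A batch of preparation and the stage cannot be told apart. Pou5f1 was lower after 4 or 6 somites on each of the 3 shared plate numbers, at −1.24 for 6 against 4 somites, −3.82 for 8 against 6 and −2.36 for 8 against 4, and every plate number of 8 and 10 somites with at least 20 cells had a smaller share of cells with a read (0.264% to 1.82%) than every one of 4 and 6 (5.32% to 43.0%). The exception was 10 against 8 somites on the second of these numbers, at 0.836 on 24 and 47 reads. A batch common to all cells of a plate number would not give the lower ratios. However, the spike-in shares on the first 2 of these numbers leave open that their cells were not prepared as 1 batch, and on the one with like spike-in shares the 15 cells of 8 somites held 11 reads, with a read in 33.3% of them against 38.0% of the 92 cells of 4 somites without thinning. A loss of transcription with stage, which the design names, stays among the open explanations and may account for the pattern, with no replicate embryo to test it.

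Y-linked genes were detected and Xist was nearly absent at 8 and 10 somites, so a difference in the sex of the pooled embryos is a candidate explanation for differences of X-linked genes such as Pim2. The stages differed in this way on shared plate numbers too. On the one shared by 6, 8 and 10 somites Xist was seen in 84.7%, 0.943% and 0% of cells. Ddx3y was seen there in 0%, 43.4% and 56.4%. On the one shared by 4 and 8 somites the shares were 76.1% and 0% for Xist and 0% and 46.7% for Ddx3y. Ratios within these plate numbers, and both chains of 10 against 4 somites, thus did not hold sex fixed. The median log2 ratio of 175 X-linked genes, 10 against 4 somites, differed by −0.04 (−0.044) from that of 5122 autosomal genes, where random sets of genes ranged from −0.053 to 0.052, so an effect of the size predicted (0.1 or more) was not seen but a smaller one stays open. The ratio of −5.65 for Pim2 exceeds a 2-fold difference in dosage. No other explanation was tested for the sex difference itself.

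The plates of 6 somites differed in neural crest genes. The share of cells with Sox10 on them was 90.9%, 65.3%, 24.9%, 7.22% and 36.7% at an equal 50000 reads, a span of 83.7 percentage points, so unequal depth in total reads is argued against. Those reads include Rn45s, with median shares of 45.9% to 64.9% on these plates, so depth on other genes was not equal. In the same order, median detected genes were 10142.5, 8095, 6284, 6180.5 and 7244. Median spike-in shares were 0.238%, 0.236%, 2.04%, 2.80% and 0.674%. The plates thus ranked alike by Sox10 and by detected genes, and a difference in library quality was not tested. Without the cells of other types, surface ectoderm-like and endothelial-like, the span was 81.8 points. These types made up at most 14.44% and 10.11% of cells on any of these plates, too few to give the span alone. Leaving them out cannot decide on the mix of the other cells, as clusters without a name were kept. Those clusters held 72.73% and 65.28% of cells on the plates with Sox10 in 90.9% and 65.3%, and 17.43% to 20% on the others. A different mix of cells thus stays open. Embryos of slightly different age, or regions of the head dissected differently, may lie behind the span, but no biological explanation was tested, as the labels give neither.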

How the results depend on the processing

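Alternatives that leave Rn45s out, of totals, thinning or clustering, and the route within plates by way of 8 somites were chosen after seeing the data. Of 2074 list medians under alternatives, 1880 moved by less than the plate SD, 187 by more, and 7 reversed. A ratio was counted as reversed where its sign turned and its size in all cells was at least 1. Of 2307 values of named genes, 2036, 243 and 28 did so, and of 788 shares 590 stayed in their interval, 198 left it and 0 reversed. At any size, the sign turned for 178 list medians and 61 values of named genes, 24 and 23 of them within plates, such as Tcf7 for 10 against 4 (0.858 to −0.76). The cause was not tested for any of these. Some of the values that stayed were fixed in advance. Leaving out a plate number without cells of the stages concerned cannot change a ratio or a share. Within plates alone, 73 of 106 list medians moved by less than the plate SD, 31 by more, and 2 reversed. Of 120 values of named genes, 40 stayed, 68 moved and 12 reversed there. The filter on cells, the added reads and the mean per cell left every list median within its plate SD. What depth limits is the share of cells with rare transcripts. No ratio was formed where both sums held at most 3 reads, a rule added after the results were seen. From the added reads alone, the erythroid medians would have been −8.24 for 10 against 4 and −0.59 for 6 against 4 within plates, and −1.50 for 6 against 4 and 5.14 for 8 against 6 without 1 plate number. Hba-x, Hbb-bh1 and Hbb-y would have been −8.24, −8.46 and −7.89 within plates, and Hba-x 1.30 and Hbb-bh1 −0.28 without that plate number. By way of 8 somites they would have been −2.615 for the erythroid median and Hba-x, −2.737 for Hbb-bh1, −0.19 for Hbb-y, 3.03 for Fgf5 and 1.97 for Tie1.

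Within plates, the median for 10 against 4 somites was 0.93 for neural crest specifiers, 1.26 for ectomesenchyme, −0.63 for neuroepithelium and −0.13 (reversed) for neuron and glia, and the neural crest specifier median for 8 against 6 was 0.33 and the endoderm median for 6 against 4 −0.01 (−0.0102, reversed). Genes of at least 2-fold in all cells that reversed within plates, 10 against 4, were Col3a1 (−0.82), Egln3 (−0.80), Egr1 (1.203), Fos (1.55), Foxa1 (−1.25), Hes5 (−0.38), Id1 (−0.26), Nes (−0.56), Pdk1 (−0.12), Spry4 (−0.92), Tbx1 (−1.29) and Vim (−0.04, −0.0382). Within plates by way of 8 somites, over 15 cells of that stage, the medians for 10 against 4 were 1.435 for neural crest specifiers, −0.24 (−0.2385) for neuroepithelium, −0.01 (−0.01095, reversed) for ectomesenchyme and −7.084 (reversed) for the cardiac list, whose single gene is Actc1. Pou5f1 was at −1.52, Nanog at −2.31, Sox10 at 2.28 and Pim2 at −3.09, and Actc1 (−7.084), Btg2 (0.2826), Col3a1 (−8.094), Egr2 (7.349), Esam (−4.028), Id1 (−0.0175), Sox17 (−0.4109) and Tbx1 (−2.868) reversed. With equal weight per plate number, 10 against 4, ectomesenchyme was 2.602 and neuroepithelium −0.41, and Emcn (−0.56), Sox17 (−0.46) and Tbx1 (−0.66) reversed. With no minimum RPM the cardiac median for 10 against 4 reversed to −1.54. The neuroepithelium median without Rn45s in the totals was −1.06 for 10 against 4, −0.41 for 10 against 8 and −0.29 for 8 against 6. With DESeq2 size factors these were −1.05, −0.40 and −0.25, and with TMM factors −0.38 for 10 against 8 and −0.28 for 8 against 6, so the sign for 8 against 6 turned.

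Leaving out 1 plate number at a time, the medians for 10 against 4 ranged from 2.10 to 2.623 for ectomesenchyme, from −1.24 to −0.27 for neuroepithelium, from −1.53 to −0.61 for core pluripotency and from 2.42 to 3.33 for neural crest specifiers. For 6 against 4 they ranged from −1.16 to −0.22 for core pluripotency and from −0.56 to −0.23 for neuroepithelium. For 8 against 6 they ranged from −0.76 to 0.15 for core pluripotency, from 0.06 (0.060) to 0.41 for neuroepithelium and from −0.52 to 1.80 for ectomesenchyme. For 10 against 8 they ranged from −0.03 (−0.0344) to 1.17 for neural crest specifiers, from −0.94 to −0.35 for neuroepithelium and from −7.71 to 0.32 for the erythroid genes. For genes, 10 against 4, the ranges were −1.82 to 0.14 for Btg2, −3.00 to 3.17 for Egr1, −2.82 to 3.27 for Egr2 and −2.99 to 2.89 for Fos, and for 8 against 6 Cnn2 ranged from −0.37 to 2.184.

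The share of cells with Pou5f1 at 4 and 6 somites was 6.36% and 2.28% at 3 reads or more, 45.5% and 23.56% at 200000 reads, 58.6% and 30.2% without thinning, and 41.8% and 18.9% at 50000 reads without Rn45s, and it ranged from 13.04% to 43.0% and from 9.77% to 15.2% without 1 plate number. The share of mesenchymal-like cells at 10 somites was 0 when centred per plate and 0 without Rn45s, and it ranged from 0 to 16.4% without 1 plate number.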

Other observations

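Cells with Pou5f1 were unevenly spread over the clusters, a reading chosen after the clusters were seen. At 4 somites Pou5f1 stood at 16.3 RPM in the 136 neuroepithelial-like cells, 41.9% of which had a read at 50000 reads, and at 1.37 RPM in the 22 early crest-like cells, of which 0 had one. At 6 somites the values were 6.33 RPM in 308 neuroepithelial-like cells (17.9% with a read) and 2.31 RPM in 184 early crest-like cells (7.61%). The classes were unevenly spread over the plates, since 95 of the 136 and 2 of the 22 cells came from the plate number of 4 somites with the larger Pou5f1 share. On the other one Pou5f1 was at 4.59 RPM in 41 neuroepithelial-like cells (21.95% with a read) and 1.026 RPM in 20 early crest-like cells (0 with one). At 6 somites the 2 values were 5.01 and 2.63 RPM, 9.48 and 3.02 RPM, and 1.77 and 1.51 RPM on the 3 plate numbers with at least 19 cells of each class. Surface ectoderm-like cells stood at 10.2 RPM at 4 somites and 2.86 at 6. In early crest-like cells of 8 and 10 somites Pou5f1 was at 0.173 and 0.207 RPM. Nanog was at 7.90 RPM in neuroepithelial-like cells and 0.702 in early crest-like cells of 4 somites. The cluster led by Fos held 795 of its 1171 reads in the neuroepithelial-like cells. Sox10 in early crest-like cells was at 51.3 RPM at 4 somites, 101 at 6, 290 at 8 and 198 at 10. These values do not follow like cells, as the early and late stages filled different early crest-like clusters. A cluster without a name, outside that class, had Sox10 at 260 RPM in 58 cells of 6 somites and 319 in 45 of 8.

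The 4 neuroepithelial-like clusters differed in the genes that ranked highest in them, which were read without a test of what the genes share. In a cluster of 190 cells these were Fezf1, Foxd4, Rax and Irs4, with 48 cells of 4 somites and 116 of 6. In another, of 156 cells, they were Hes3, Fam181b, Fgf15 and En1, with 29 and 117 cells of those stages. In another, of 88 cells, they were Msx3, Vgll3, Irx2 and Sfrp2, with 0 cells of 4 somites, 11 of 6, 35 of 8 and 42 of 10. The last, of 123 cells, was led by Fos, Pmaip1 and Egr1, had 59 cells of 4 somites, 64 of 6 and 0 of the later stages, and drew 78.0% of its cells from 1 plate number. Among the clusters without a name, a cluster of 53 cells was led by Foxa1, Nkx2-9, Foxa2 and Ptch1, a cluster of 95 cells had Tbx1 and Col3a1 among its highest, and a cluster of 115 cells, led by Actc1, Acta2, Cdkn1c and Sox10, carried raised globin genes, with 73.9% of its cells from 1 plate number. That cluster of 115 cells also raised 5 early crest markers, and its cells are not in the early crest-like class. A cluster of 68 cells, 66 of them from 10 somites, was led by Crabp1 and ribosomal protein genes and had a median Rn45s share of 32.4%.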
